A study of Nematostella vectensis with 4 samples.

How the data were processed

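RNA was sequenced from cells of the adult mesentery of the sea anemone Nematostella vectensis, the internal fold of the body wall that carries retractor muscle, digestive and reproductive tissue. The animals carried a transgene in which mCherry, a red fluorescent protein, is driven by regulatory sequence of a myosin heavy chain gene. Per the labels' protocols, mesenteries of 8 adults were taken, their distal-most tissue was removed, the rest was dissociated with papain and collagenase, and cells were sorted by fluorescence into TRIzol as mCherry+ or mCherry- populations. A polyA-selecting library kit was used. There were 4 libraries, 2 labelled mesentery muscle and 2 labelled mesentery non muscle, and these labels set the groups. The mCherry+ sort was taken to be the muscle fraction and the mCherry- sort the non-muscle fraction, from the wording of the design text. The design was run in duplicate, but nothing says which animals went into which duplicate, so the p-values measure the spread between these libraries, which may be partly technical. Replicate numbers below were given in accession order and do not pair the libraries.

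The authors deposited a table of raw counts, whole numbers of reads per gene model, with 1 column per library and no pooling. The submitters' processing notes name cutadapt and TopHat without versions. The read counter, its strand setting, the genome build and the source of the gene models are not given in the sources used here, so reads shared between near-identical copies, overlapping gene models or antisense partners may have been split or dropped, and a fold change of such a gene model is uncertain. The table held 25729 gene models with NVE identifiers, of which 1925 had 0 counts in all 4 libraries, and no row without a gene. Every column of values was used.

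The identifiers came without gene names. They were looked up in a RefSeq gene table of assembly jaNemVect1.1, where 0 of the 25729 identifiers matched. For this reason 18 gene lists fixed before the data were examined (contractile proteins, calcium handling, cnidocytes, neurons, gland cells, germ line, cell cycle and others) were not tested, no gene function is stated, and the level of the myosin heavy chain genes, planned as a check of the sort labels, was not analysed here. The rule for named gene models, also fixed before the data were examined, then gave the highest 2 and the lowest 2 log2 fold changes. They were taken among gene models with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 10 CPM (counts scaled to a common library size, below) over the 4 libraries, and both libraries of one fraction above both of the other. There were 2442 such gene models. The rule does not say whether these conditions also hold when gene names are missing, and they were kept here. Larger log2 fold changes, up to 6.03 and down to -7.13, occurred among gene models with a mean under 1 CPM.

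Total counts per library ranged from 31813772 to 67102862. At this depth the 95% Wilson interval of any share of counts given below reached at most 0.0173 percentage points to either side. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and the number of libraries limits precision far more.

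Muscle and non-muscle libraries were compared with edgeR 4.0.16 in R 4.3.3. Gene models were filtered with filterByExpr by fraction (minimum count 10, minimum total 15), which left 17994, and libraries were scaled by TMM. The quasi-likelihood test was fitted with robust=TRUE, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are muscle over non-muscle. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. With 2 residual degrees of freedom, the test borrowed spread across gene models (median prior degrees of freedom 8.56). CPM values are TMM-scaled unless called shares of the library. Log2 ratios of single libraries were taken on CPM + 0.5, and correlations between libraries on log2(CPM + 1) with plain library totals.

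The fit was tested on simulated data for the muscle against non-muscle comparison. Counts were drawn for the 17994 gene models from the real means, library sizes and dispersions, with 100 gene models changed 2-fold and 100 changed 4-fold. The edgeR test called 2% of the 2-fold and 54% of the 4-fold changes, with 5 false calls among 17794 unchanged gene models, and its median estimates were 1.00 and 1.96 on the log2 scale. Far fewer gene models were changed than were called in the real data (8156), and the Benjamini-Hochberg threshold depends on that number. The rates of detection and of false calls therefore hold for the simulated setting, not for the real comparison.

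A mixing model, in which non-muscle replicate 1 is replicate 2 plus an added share of muscle RNA, was fitted on shares of the library as the median over the 8-fold higher gene models.

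Alternatives were RLE, upper-quartile and library-total scaling, no filter on low counts, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, limma-voom 3.58.1, edgeR's glmTreat against a fold of 2, and leaving out each library in turn. Scaling by library totals without the 50 most abundant gene models was added after seeing the data. Summaries, permutation tests and plots used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.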

Results

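To profile the muscle of the Nematostella vectensis mesentery, mCherry+ and mCherry- cells were sorted from transgenic adults and sequenced as bulk polyA RNA, with 2 libraries per fraction. The muscle libraries held 34876467 (replicate 1) and 53424952 counts (replicate 2), and the non-muscle libraries 31813772 and 67102862. A count was seen for 21552 and 22154 gene models in the muscle libraries and for 22421 and 22874 in the non-muscle libraries. Libraries of the same fraction had a Pearson correlation across gene models of 0.983 (non-muscle) and 0.988 (muscle) on log2(CPM + 1), and libraries of different fractions one of 0.904 to 0.937. Gene models are not independent replicates, so these values describe similarity only. No 2 libraries agreed within sampling noise. The chi-square per degree of freedom over gene models was 93.6 between the muscle libraries and 205 between the non-muscle libraries, so neither pair was treated as 1 library deposited more than once. This does not show that the libraries came from separate animals.

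The muscle and non-muscle fractions differed across a large part of the transcriptome, in both directions. Of 17994 gene models tested, 4262 were higher and 3894 lower in the muscle fraction, together 45.3% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among the calls, 4085 were at least 2-fold higher and 3704 at least 2-fold lower, 1703 and 1322 were at least 4-fold higher and lower, and 393 and 290 at least 8-fold. The median log2 fold change was 1.81 among the higher and -1.70 among the lower gene models. The smallest fold that was called was 0.79 on the log2 scale among the higher and 0.80 among the lower gene models. This is not a limit of detection, since some gene models with larger folds were not called. Examples are NVE10736 (log2 fold change 1.54, edgeR adjusted p = 0.070) and NVE10817 (-2.73, edgeR adjusted p = 0.053). In simulated data edgeR called 2% of 2-fold and 54% of 4-fold changes. Far fewer gene models were changed there than were called here, so these rates do not give the detection in the real comparison. The balance between higher and lower gene models depended on the scaling. Under plain library totals, which shifted the median gene model by -0.63 on the log2 scale, 2246 gene models were higher and 6873 lower, which put the higher share of the calls at 24.6% in place of 52.3%. Without muscle replicate 2, 2281 gene models were higher and 1406 lower, and without muscle replicate 1, 3271 and 2442.

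**Figure D1:**
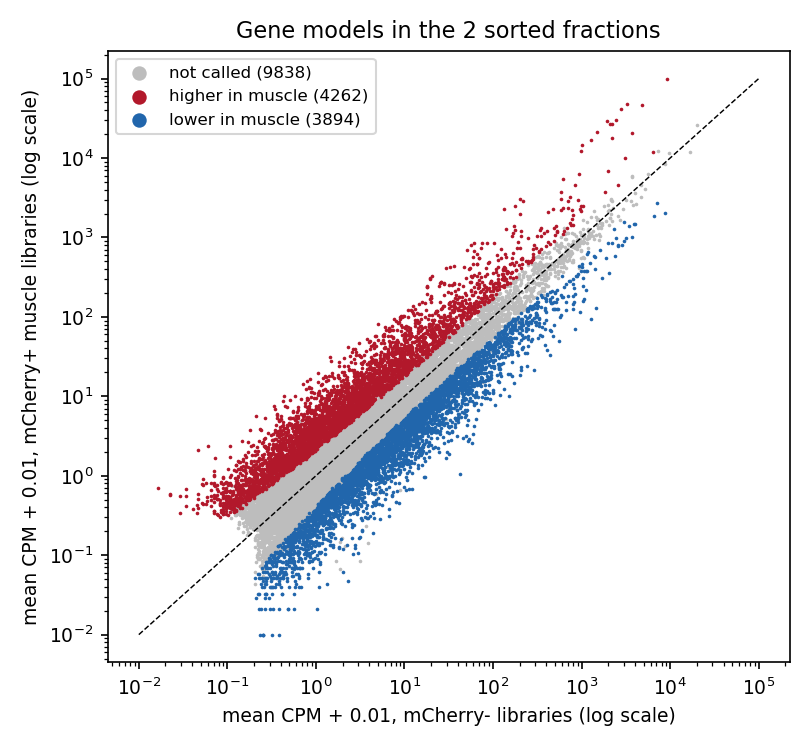
Mean CPM + 0.01 of each tested gene model in the mCherry- libraries (x axis, log scale) and the mCherry+ muscle libraries (y axis, log scale), TMM-scaled, n = 2 per fraction. Red points are the 4262 gene models higher in muscle, blue points the 3894 lower ones and grey points the 9838 not called, and the dashed line marks equal levels.

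Among gene models with a mean of at least 10 CPM, the largest differences were the following, with no function given for these identifiers. NVE863 was 22.0-fold higher in the muscle fraction, with 31.0 ± 17.1 CPM (SD, n = 2) against 1.43 ± 0.86 CPM in the non-muscle fraction (log2 fold change 4.46, SE 0.57, edgeR adjusted p = 0.00086). NVE24315 was 19.6-fold higher, with 28.0 ± 1.7 CPM (SD, n = 2) against 1.45 ± 1.10 CPM (log2 fold change 4.30, SE 0.54, edgeR adjusted p = 0.00079). In the other direction, NVE14972 was 23.1-fold lower in the muscle fraction, at 2.55 ± 0.96 CPM (SD, n = 2) against 58.5 ± 2.8 CPM (log2 fold change -4.53, SE 0.40, edgeR adjusted p = 0.00049). These 3 gene models passed the threshold under every alternative that kept all 4 libraries. Leaving out any 1 library kept their direction, but single libraries moved the folds of the higher ones. The log2 fold change of NVE863 was 5.23 without non-muscle replicate 1 and 3.74 without muscle replicate 2, and that of NVE24315 was 5.36 without non-muscle replicate 1 and 3.65 without non-muscle replicate 2. NVE11504 had the lowest log2 fold change, -5.40 (SE 1.51, edgeR adjusted p = 0.031), but its non-muscle level rested on 1 library, with 81.0 CPM in replicate 2 and 4.20 CPM in replicate 1, against 1.69 and 0.42 CPM in the muscle libraries. Its log2 fold change was -2.05 without non-muscle replicate 2 and -6.33 without non-muscle replicate 1. Without muscle replicate 1 it was -6.63, and without muscle replicate 2 it was -4.65.

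**Figure D2:**
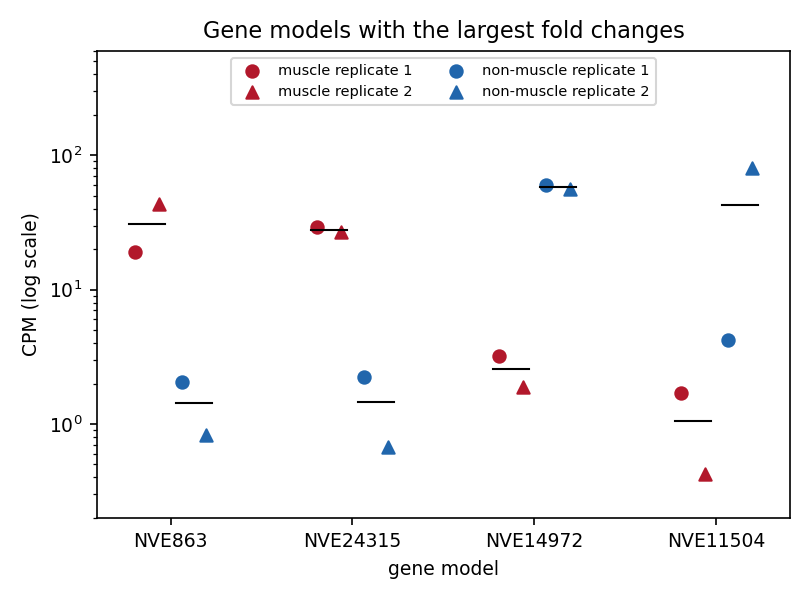
TMM-scaled CPM (log axis) in each library of the 4 gene models with the largest fold changes among those with a mean of at least 10 CPM. Circles are replicate 1, triangles replicate 2 and black bars the mean of each fraction (n = 2), with the muscle libraries in red and the non-muscle libraries in blue, and the NVE11504 values of the non-muscle libraries lie at 4.20 and 81.0 CPM.

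The muscle libraries drew a large share of their counts from a small set of abundant gene models. The 10 most abundant gene models of each library took 31.4% ± 1.7 (SD, n = 2) of its counts in the muscle fraction and 12.6% ± 0.3 (SD, n = 2) in the non-muscle fraction. For the 50 most abundant, the shares were 52.3% ± 1.8 and 29.2% ± 0.2 (SD, n = 2). The effective number of gene models, the exponential of the Shannon entropy of the count shares, was 460 ± 45 in the muscle and 1332 ± 3 in the non-muscle libraries (SD, n = 2). Both differences exceeded the spread between replicates, but an exact 2-sided permutation test of 2 libraries against 2 cannot go below p = 0.333, which is the value both gave. The most abundant gene model of the muscle libraries held 7.76% ± 0.84 of their counts and 1.15% ± 0.41 of the counts of the non-muscle libraries (SD, n = 2). Its TMM-scaled log2 fold change was 3.41 (SE 0.38, edgeR adjusted p = 0.00049), which is larger than the ratio of these plain library shares.

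**Figure D3:**
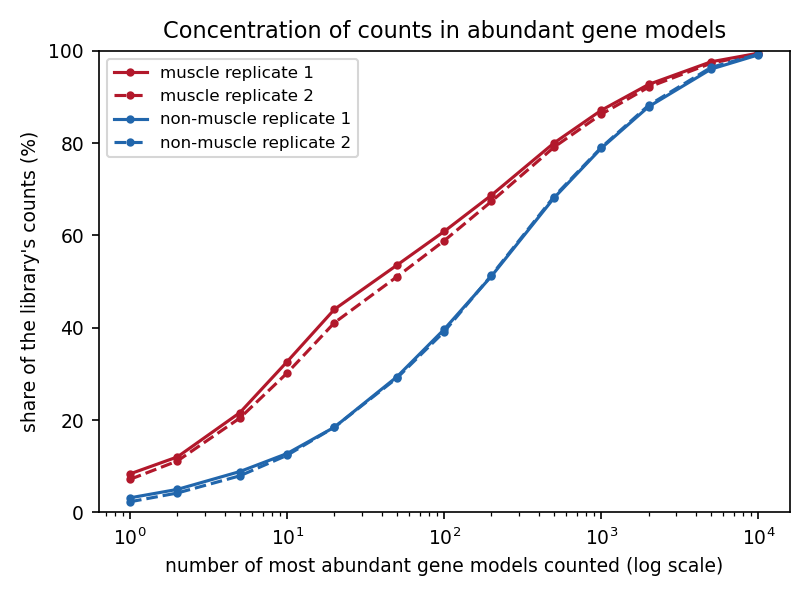
Share of each library's counts (%) held by its most abundant gene models (x axis, number of gene models, log scale), with muscle libraries in red and non-muscle libraries in blue. At 10 gene models the muscle libraries reach 32.7% and 30.2% and the non-muscle libraries 12.8% and 12.4%.

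The abundant end of the muscle transcriptome was nearly all higher than in the other fraction, whereas that of the non-muscle fraction was mixed. Of the 15 gene models with the highest mean CPM in the muscle libraries, 14 were higher there by the edgeR test, with log2 fold changes from 2.51 to 3.91, and 1 was not called (0.36). Of the 15 most abundant in the non-muscle libraries, 3 were lower in muscle, 3 were higher in muscle and 9 were not called. Their log2 fold changes ran from -2.10 to 3.41, and whether muscle RNA in the mCherry- libraries put gene models into this set was not tested. These sets were chosen on the level in 1 fraction, which favours gene models higher in that fraction. Among the 100 gene models of highest mean CPM over all 4 libraries, 37 were higher, 18 lower and 45 not called, and 16 of the higher but 0 of the lower ones differed at least 8-fold. This set is also open to gene models that are very abundant in 1 fraction alone. Gene models with a mean of at least 100 CPM were called in 48.6% of 1139 cases and those of 10 to 100 CPM in 53.6% of 4045 cases. Those of 1 to 10 CPM were called in 48.7% of 7952 cases and those under 1 CPM in 32.2% of 4858 cases.

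Summed over all calls, gene models higher in muscle took 58.3% ± 2.4 of the muscle counts and 15.7% ± 3.6 of the non-muscle counts (SD, n = 2). Gene models lower in muscle took 6.09% ± 0.08 of the muscle counts and 28.9% ± 4.3 of the non-muscle counts (SD, n = 2). The 393 gene models at least 8-fold higher alone held 37.4% ± 2.4 of the muscle counts and 4.96% ± 2.53 of the non-muscle counts, while the 290 at least 8-fold lower held 0.0882% ± 0.0036 of the muscle and 1.45% ± 0.48 of the non-muscle counts (SD, n = 2). These gene models were selected on the same libraries, so the shares describe the size of the called groups and are not a separate test.

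The gene models higher in muscle were also counted in both mCherry- libraries, at unequal levels. For the 144 gene models at least 8-fold higher with a mean of at least 10 CPM, the median share of the library in non-muscle replicate 1 was 19.2% of the mean muscle share, and in replicate 2 it was 9.77%. On the same scale of plain library shares, gene models not called and within 1.4-fold stood at 163% and 155% of the muscle share. Of the 144 gene models at least 8-fold higher, 99.3% had a higher TMM-scaled CPM in non-muscle replicate 1 than in replicate 2, with a median log2 ratio of 0.77. Gene models not called and within 1.4-fold are termed unchanged below, which holds under TMM scaling only and does not show equal levels. Among these 1455 gene models, 40.7% were higher in replicate 1, with a median log2 ratio of -0.10. The difference of these medians was 0.87 (95% bootstrap interval over gene models 0.775 to 0.999, which treats gene models as independent). Of the 288 gene models 4- to 8-fold lower in muscle, 20.8% were higher in non-muscle replicate 1, with a median log2 ratio of -0.70. Of the 65 at least 8-fold lower, 41.5% were higher in replicate 1, with a median of -0.31. Relative to the unchanged gene models, the median share ratio of these 65 lay at -0.22 (95% bootstrap interval -0.88 to 0.15), too wide to tell it from 0 or from the -0.61 of the 4- to 8-fold lower class. In the muscle libraries, the median log2 ratio of replicate 1 to replicate 2 ran from -0.03 in the 8-fold higher class to 0.21 in the 8-fold lower class. Unchanged gene models stood at 0.04 there. No muscle median was as large in size as the 0.77 and -0.70 of the non-muscle libraries.

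**Figure D4:**
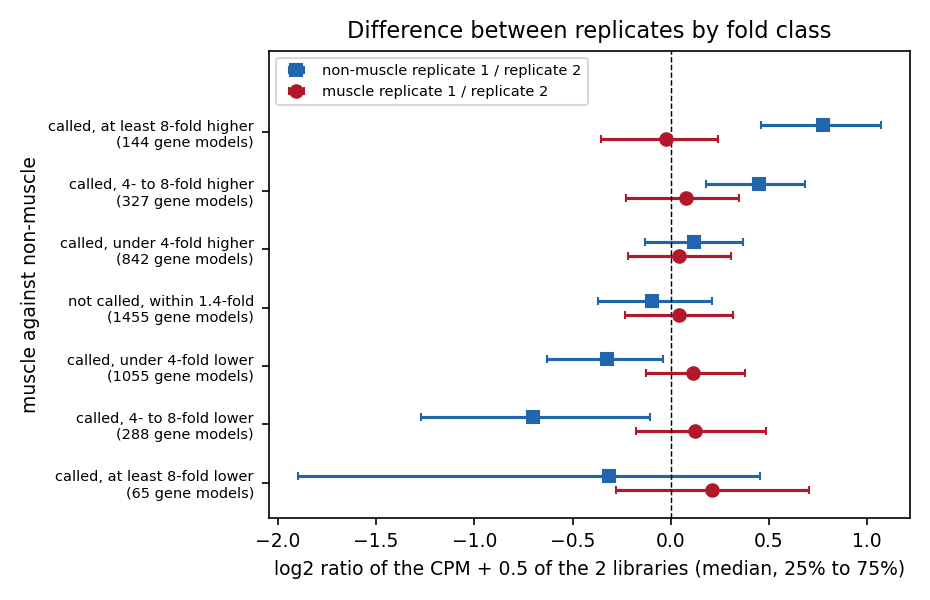
Log2 ratio of the CPM + 0.5 of replicate 1 to replicate 2 (x axis) for gene models grouped by their fold change of muscle against non-muscle (y axis), for those with a mean of at least 10 CPM. Points are medians and bars run from the 25% to the 75% quantile over gene models; the non-muscle ratio (blue) falls from 0.77 in the 8-fold higher class to -0.70 in the 4- to 8-fold lower class and lies at -0.31 in the 8-fold lower class, while the muscle medians (red) stay between -0.03 and 0.21.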

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

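The counts of calls moved with the scaling, with the libraries included and with a test against a minimum fold. Against 4262 gene models higher and 3894 lower in the muscle fraction, plain library totals gave 2246 and 6873 (at least 2-fold: 2132 and 6558 against 4085 and 3704). The added scaling by totals without the 50 most abundant gene models, chosen after seeing the data, gave 3866 and 4018. Testing against a fold of 2 with glmTreat left 1939 higher and 1369 lower, a stricter question by construction. Leaving out each library in turn gave 2281 to 4561 higher and 1406 to 4333 lower, and at least 2-fold 2281 to 4472 higher and 1406 to 4124 lower. The lowest values came without muscle replicate 2, and without muscle replicate 1 the lower count was 2442; the cause was not tested, and the lone library of a fraction is then assumed to vary like the other fraction. RLE and upper-quartile factors, both filters, DESeq2 (3902 and 3696) and limma-voom (4221 and 3698) stayed within 1.5 times of every count. NVE11504 missed the threshold under library totals (adjusted p = 0.11), no filter (0.25) and glmTreat (0.065). The difference of 0.87 between the non-muscle replicates in the 8-fold higher class was 1.05 at a mean of at least 100 CPM. No fit with pairs was made: the library numbers 20953 to 20956 alternate between muscle and non-muscle, but the labels do not say that neighbouring numbers share a dissociation. The tests of gene lists and their alternatives were not run, since the identifiers matched no gene names.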

Other observations

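The tests on the ratios between non-muscle replicates, on totals without the 50 most abundant gene models and on neighbouring numbers were chosen after the result was seen, whereas scaling by library totals was planned. The lower side of the comparison varied more between the mCherry- libraries than the upper side. Among the 65 gene models at least 8-fold lower in muscle with a mean of at least 10 CPM, the log2 ratio of non-muscle replicate 1 to replicate 2 had an SD of 1.36 over gene models, against 0.45 for the 144 gene models at least 8-fold higher. The 25% and 75% quantiles of this ratio were -1.90 and 0.45 in the 65 gene models. These 65 gene models passed the filters through a high non-muscle level, which 1 high library can give. The 144 passed through a high muscle level, so the SDs of 1.36 and 0.45 are not a matched comparison. In the muscle libraries, the SD was 0.68 for the same 65 gene models and 0.49 for the 144. NVE11504 is an extreme case, with 4.20 and 81.0 CPM in the non-muscle libraries.

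Nearly all gene models strongly higher in muscle had more counts in non-muscle replicate 1 than in replicate 2. A difference in scaling between these libraries moves every gene model alike. On its own it would not open the difference of 0.87 between the median log2 ratios of the 8-fold higher and the unchanged gene models. This follows from how scaling works, and the 0.87 is part of the pattern, so it is no separate test. Low expression of each gene model on its own in non-muscle cells would leave the ratios on either side. The 99.3% higher in replicate 1 shows that nearly all of these gene models shared the excess. It is the pattern itself, however, and no separate test of that explanation. Muscle RNA carried into the mCherry- libraries, in a larger share in replicate 1, may account for part of the excess but stays open. An added share of 10.03% was set on the 8-fold higher class, and no interval was computed for it. For the 4- to 8-fold higher class, mixing replicate 2 with this share of muscle RNA predicts a median log2 ratio of 0.43 against unchanged gene models. That lies below the observed 0.55 and outside its 95% bootstrap interval over gene models (0.48 to 0.59). For the class under 4-fold higher the mixing predicts 0.16, also below the observed 0.21 and outside its interval (0.17 to 0.26). Mixing with this 1 share thus leaves part of the excess in both classes unaccounted for. For the 8-fold higher class it gives 0.93, where 0.87 was observed (0.78 to 1.01). The share was set on this class, so this value is no test of the mixing. The same mixing predicts -0.082 for the 4- to 8-fold lower class, where -0.61 was observed (-0.74 to -0.46), and -0.061 for the class under 4-fold lower, where -0.23 was observed (-0.28 to -0.18), which argues against dilution as the whole cause of the shift in these classes. For the 8-fold lower class the predicted -0.090 lies within the observed interval (-0.88 to 0.15), and whether other cell types differed in share between the mCherry- libraries was not tested.

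The share of calls that were higher in muscle dropped to 24.6% when libraries were scaled by their totals. With the 50 most abundant gene models left out of the totals, 49.0% of the calls were higher, near the 52.3% under TMM. This follows from the shares of counts that these gene models hold in each fraction and is no separate test of whether a few gene models taking most of the muscle counts caused the drop. A lower output of most gene models per muscle cell, which would make the shift of -0.63 on the log2 scale real, cannot be told apart from such a concentration of counts, because the files hold no RNA amount per cell and no added standard.

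Gene models with neighbouring NVE numbers had similar fold changes. Over 13810 pairs of tested gene models with consecutive numbers, the log2 fold changes had a Pearson r of 0.231 and a Spearman rho of 0.236 across gene models, and r fell to 0.083 at a distance of 2 numbers, 0.038 at 3 and 0.0095 at 5. In 100000 random orders of the numbers the highest r was 0.036 at a distance of 1 and 0.042 at a distance of 2 (permutation p = 1e-05 for both r and rho at both distances, the smallest these can give), which argues against a random order. Of the consecutive pairs with both members called, 69.1% had the same direction, against 50.1% for independent calls. Single genes split over a pair of gene models with consecutive numbers would give no relation at a distance of 2, so they do not account for that part. A gene split over numbers that are not consecutive is not covered by this. Consecutive splits may contribute to the r of 0.231, as may genes split over more models, neighbouring copies of a gene, or neighbours regulated together. Reads shared between overlapping gene models may also contribute, since the read counter and its strand setting are not given. These were not tested, since the positions of the gene models were not used here.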
